A study of Mus musculus with 6 samples.

How the data were processed

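RNA was measured in 6 libraries, 3 WT and 3 KO, of sorted fluorescent cells from telencephalon at E14.5. Per the labels' protocols, poly-A RNA was taken from 100 ng of total RNA, amplified by 15 PCR cycles, pooled as 6 libraries and read as single reads of 36 cycles. The submitters' processing notes name TopHat 1.2.0, HTSeq 0.5.3p3, DESeq 1.2.2 and genome build mm9, with no role or order. The gene annotation and the use of strand are not given in the sources used here.

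The deposited count files gave whole read counts per gene, not normalized, for 36291 gene rows, and the authors' count table of the whole series held the same counts in all 36291 rows. Rows that name no gene stayed out of library sizes and tests, the unassigned row taking 19.75 to 21.77% and the ambiguous row 1.94 to 1.99% of all counts in a library. The authors' deposited table of the comparison gave, per the file headers, a fold change as a ratio, its log2, and p-values before and after adjustment. Its headers call the groups A and B, so its mean columns were not used, and its folds were read as KO over WT because each of the 777 calls it shares with the edgeR fit had the same sign. No per-sample column was left without a sample.

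Gene symbols were used as the files give them, and 27099 of the 36291 (12283 of the 13835 tested) were found in the reference gene names. The reference annotation is of a later build than mm9, so no coordinates are printed, and its gene order (GRCm38.p6) served only to find neighbouring genes.

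Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr with a minimum count of 10, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05 over 13835 genes. The SE is the log2 fold change divided by the square root of the F statistic, and can be too small where counts are few. Gene lists were tested two-sided with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 20 lists with at least 5 tested members out of 24 lists written. The design, lists, alternatives and named-gene rule were fixed before the data were examined. The rule took Zeb2, 7 genes chosen from the study's title and the field, the 12 largest changes in each direction (adjusted p under 0.05, mean of at least 5 CPM, no overlap between genotypes), and up to 4 called members per list by lowest p, or 2 where none was called. Other called list members and genes outside the lists were chosen after their values were seen.

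Depth was 8323531 to 11069437 gene counts per library, and the common biological coefficient of variation was 9.26%. Replicates of a genotype differed beyond sampling noise, with a chi-square per degree of freedom of 5.79 to 10.12 between WT and 3.65 to 4.51 between KO libraries. Nothing in the labels says that libraries came from separate embryos, so p-values measure the spread between these libraries. Libraries sharing a K number deviated together from their group means (correlation across genes 0.256 for K77, 0.197 for K79 and 0.175 for K80, against -0.176 to -0.00936 for other pairs). Deviations within a genotype cancel out, so the other pairs must be negative on average once same-numbered pairs are positive, and give no separate contrast. All 3 same-numbered pairs exceeded the 0.1 set as the limit, so the number was taken to pair libraries. The blocked fit is given where it changes a call or moves a count by over 1.5 times.

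The tests were tried on simulated counts for the KO against WT comparison, where in a step of 13680 genes the unblocked fit recovered 55.1% of genes changed 1.5-fold, 81.2% at 2-fold, 97.9% at 3-fold and 100% at 4-fold, with 4.8% false calls. In a step of 13685 genes with none changed it made 3 calls. In a list test on 13690 simulated genes, camera found the raised list (adjusted p = 4.28e-68) and called 0 unchanged lists. In the step of 13680 genes the blocked fit recovered 53.1, 83.3, 97.9 and 100% with 7% false calls. Simulated genes were drawn independently of each other and with no pairing by K number. The simulation therefore could not show how camera behaves with correlated genes, or the blocked fit with paired libraries.

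Alternatives were RLE size factors, the DESeq2 1.42.0 Wald test, limma voom, no filter or 1 CPM in 3 libraries, the K number as a block, other thresholds, each library left out, erythroid, mitochondrial and sex-linked rows dropped, an estimated correlation and fry. Leaving out both K79 libraries, a blocked fit with an estimated correlation and a list of imprinted genes were added after the data had been seen. Sequence reads were not analysed here.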

Results

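The series asked how the transcription factor Zeb2, called Sip1 in its title, bears on the migration of cortical interneurons. These neurons are born in the ventral forebrain, largely in the medial ganglionic eminence (MGE), and travel to the cortex. Messenger RNA was sequenced from green fluorescent cells sorted out of the telencephalon of Swiss mouse embryos at E14.5, the fluorescence marking cells in which an Nkx2-1 Cre driver had acted. There were 3 wild-type (WT) and 3 knockout (KO) libraries, each carrying 1 of the numbers K77, K79 and K80, with 1 library of each genotype per number. The labels did not say what the number stands for. Reads assigned to genes totalled 9196406 in WT K77, 10288651 in WT K79 and 10558698 in WT K80. The KO totals were 8323531 for K77, 10264062 for K79 and 11069437 for K80. Levels are given as CPM, the counts scaled to a common library size, as mean ± SD with n = 3 libraries per genotype, and log2 fold changes are KO against WT with the standard error (SE).

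Zeb2 itself was lower in each KO library than in each WT library. The WT libraries held 6468 (K77), 5350 (K79) and 8094 (K80) Zeb2 counts and the KO libraries 2856, 2759 and 3391 in the same order. The level fell from 662 ± 133 to 308 ± 35.6 CPM, a log2 fold change of -1.11 (SE 0.138, edgeR adjusted p = 0.00116). The labels did not give the deleted part of the gene, so reads from the rest of the transcript are included in these counts. Zeb1, the related zinc finger homeobox gene, was higher by 0.32 (SE 0.0722, adjusted p = 0.0281), a call lost without WT K77, KO K77, KO K79 or WT K80 (adjusted p 0.058 to 0.128).

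Cells sorted from KO embryos kept the MGE-lineage genes Lhx6 and Sst at levels not told apart from WT, while other genes of cortical interneurons fell steeply. Lhx6, a transcription factor of MGE-derived interneurons, stood at 1057 ± 117 CPM in WT and 1096 ± 147 in KO (log2 fold change 0.05, SE 0.104, edgeR adjusted p = 0.852). Sst, which encodes somatostatin, differed by 0.06 (SE 0.135, adjusted p = 0.881). The transcription factor gene Maf fell 8.38-fold from 210 ± 64.2 CPM. The chemokine receptor genes Cxcr4 and Cxcr7, whose ligand guides migrating interneurons, fell 8.13-fold and 3.49-fold. The netrin receptor gene Unc5b rose 5.28-fold, from 12.5 ± 4.71 to 65.7 ± 4.14 CPM.

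Across the 13835 genes tested, 867 changed by edgeR at adjusted p under 0.05, 504 higher and 363 lower in KO. Of these, 163 rose and 98 fell by at least 2-fold. With the K number as a block the counts were 848 higher and 615 lower, 1463 in all, and the 867 genes kept their sign and call. Among called genes 866 had no overlap between KO and WT libraries, which the call itself favours because both rest on the same counts. Of all tested genes 23.2% had no overlap, against 10% by chance. The total was 528 without WT K77, 498 without KO K79 and 445 without KO K80.

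**Figure D1:**
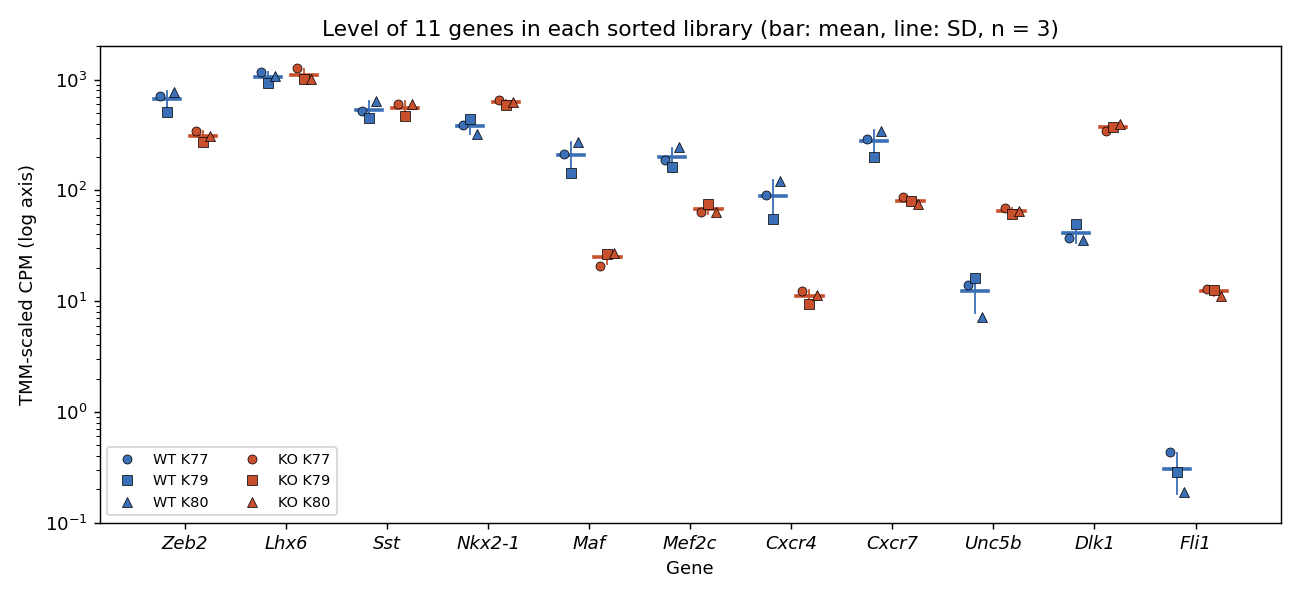
Level of 11 genes in each library, in TMM-scaled CPM on a log axis, with WT in blue and KO in orange, a marker shape per K number, a bar at the mean and a line for the SD (n = 3). Lhx6 and Sst overlapped between genotypes, Maf, Mef2c, Cxcr4 and Cxcr7 were lower in each KO library, and Unc5b, Dlk1 and Fli1 were higher in each KO library.

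The steepest rises among genes above 5 CPM on average included the ETS transcription factor gene Fli1, the imprinted gene Dlk1, which encodes a transmembrane protein related to Notch ligands, and the netrin-G1 gene Ntng1. Dlk1 rose from 41.0 ± 7.64 to 373 ± 26.2 CPM (log2 fold change 3.18, SE 0.117, edgeR adjusted p = 1.86e-06). Fli1 rested on 4, 3 and 2 counts in WT K77, K79 and K80. It stood at 12.3 ± 1.05 CPM in KO, a log2 fold change of 5.30. Its 95% interval of 4.70 to 5.89 comes from the F statistic and is likely too narrow at so few WT counts. Fam46a (2.80), Ntng1 (2.63), Unc5b (2.40), Zim1 (2.22), the serotonin receptor gene Htr1a (2.19), Syt6 (2.13) and Adamtsl2 (2.09) rose as well, in log2 fold change. Sulf1 (2.29), Fam70a (2.16) and Aifm3 (2.04) were also called, but each lost its call without WT K77, KO K79 or KO K80. Fam70a and Aifm3 lost theirs without WT K80 too, and adjusted p rose to 0.0628, 0.158 and 0.158 for the 3 genes. Above the same mean level, the deepest falls were in the diacylglycerol kinase gene Dgkg (-3.53), Nxph2 (-3.50), Maf (-3.07), Cxcr4 (-3.02), the thrombospondin gene Thbs1 (-3.00) and the potassium channel gene Kcnh3 (-2.89). Pdgfra (-2.29), Zbtb16 (-2.21), Rpp25 (-2.18), Ror2 (-2.10), 3110082D06Rik (-2.06) and Cspg4 (to 2.78 ± 0.818 CPM) completed the 12.

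Gene lists fixed before the data were examined were tested with camera, 20 lists in all, and 7 passed an adjusted p of 0.05 with a preset correlation between genes. None of the 7 passed when that correlation was estimated from the data, so the counts of members carry the description and that p is given for each. For scale, edgeR called 6.27% of all tested genes in the unblocked fit, and called 3.64% higher.

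Genes of MGE and cortical interneuron identity were mostly lower. Of 30 tested, 16 fell, 5 rose and 9 were not called, or 17 lower and 6 higher adjusted over the list alone. Mef2c fell by 1.56 on the log2 scale, the neurexophilin gene Nxph2 by 3.50 and the vesicular GABA transporter gene Slc32a1 by 0.53, while Nkx2-1 rose by 0.70 and Gad2 by 0.56. The camera adjusted p was 4.18e-14, and adjusted p = 0.456 with an estimated correlation. Without KO K80, 11 members fell, and 3 rose without WT K77, KO K77 or KO K79. In WT K79 the levels of Maf (145 CPM) and Cxcr4 (55.2 CPM) were the nearest of the WT libraries to KO, and without that library 17 members fell and 6 rose. Dlx6 and its overlapping antisense transcript Dlx6os1 moved in opposite directions (-0.40 and 0.39) and are uncertain, because the strand used in counting is not given in the sources used here.

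Genes of subpallial and striatal fates of the MGE lay above WT in camera (adjusted p = 0.000798, and adjusted p = 0.543 with an estimated correlation). Of 19 tested, 3 rose, 0 fell and 16 were not called, against 9 higher and 1 lower adjusted over the list alone and 9 higher and 1 lower in the blocked fit. The 3 were the LIM-homeobox gene Isl1 (log2 fold change 0.96, SE 0.227), Gbx1 (0.64) and Lmo3 (0.52). Without WT K79, 9 members rose. Without KO K80 edgeR called 0 members higher, and without WT K77, KO K77, KO K79 or WT K80 it called 1, with 1 lower without KO K79. Isl1 lost its call without WT K77, KO K79, KO K80 or WT K80 (adjusted p up to 0.153), Gbx1 without any library but WT K79 (up to 0.0958) and Lmo3 without KO K77 or KO K80 (up to 0.0938).

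Markers of other forebrain lineages moved in a few members each. In the list of the lateral eminence and striatal projection neurons, 2 of 22 rose, 1 fell and 19 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.901). The opioid peptide gene Penk rose by 1.67 and Sp9 fell by 1.12, while Meis1 (0.37) lost its call without WT K77, KO K77, KO K79 or WT K80 (adjusted p up to 0.148), and 1 member rose without WT K77, KO K79 or WT K80. In the list of the caudal eminence and preoptic area, 3 of 10 fell, 0 rose and 7 were not called, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0546, and 0.0295 without KO K79 or 0.0438 without KO K80). Nr2f1 fell by 0.68 and Calb2 by 1.44, and Htr3a (-1.36) lost its call without KO K79, KO K80 or WT K80 (adjusted p up to 0.0631). In that list 1 member rose with the block or without WT K79, and 2 without KO K77. Of 24 cortical glutamatergic genes 3 fell, 1 rose and 20 were not called, with 2 higher and 3 lower adjusted over the list alone and in the blocked fit. Camera gave an adjusted p of 0.00804 for lower levels in that list, 0.259 without WT K77, and adjusted p = 0.616 with an estimated correlation. Its called members were Cux2 (-1.82), Mef2c (-1.56), which is also in the interneuron list, Cux1 (-0.36) and Unc5d (0.66). Further calls in the authors' deposited table included Tbr1 (-0.43), Neurod2 (-0.43), Neurod6 (-0.39) and Lhx2 (-0.37) lower and Nfib (0.46) higher, each with overlapping KO and WT libraries. Which cells carried these transcripts was not tested. Cux1 lost its call without WT K77 or any 1 KO library (adjusted p up to 0.0694) and Unc5d without WT K77, KO K79, KO K80 or WT K80 (up to 0.174). Without WT K80, 7 members of that list fell, and 0 rose by edgeR without WT K80 or KO K80.

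The cell cycle genes that changed fell by small amounts. Of 40 tested, 10 fell, 0 rose and 30 were not called, against 26 lower adjusted over the list alone and 23 lower in the blocked fit. The median log2 fold change was -0.32 (camera adjusted p = 7.61e-12, and adjusted p = 0.543 with an estimated correlation). Mcm6, part of the replicative helicase, fell by 0.37, and the cyclin gene Ccna2 fell by 0.38. Ccna2 lost its call without KO K80 (adjusted p = 0.0568), Rrm2 (-0.53) without KO K79, KO K80 or WT K80 (up to 0.138) and Mcm3 (-0.34) without any library but WT K77 (up to 0.132). The number of lower genes was 3 without WT K79 or WT K80, 2 without KO K79 and 1 without KO K80. Radial glia and ventricular zone genes went both ways, with 4 of 31 higher, 2 lower and 25 not called, and 6 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.901). In that list the blocked counts were 7 and 4. Gsx2 rose by 0.80 (adjusted p = 0.0512 without KO K77), and Ccnd2 (-0.43) lost its call without WT K77, KO K79 or KO K80 (adjusted p up to 0.0995). Only 2 of them rose without KO K77, KO K79 or KO K80, and 1 fell without WT K77, KO K79 or KO K80.

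Oligodendrocyte precursor genes included some of the deepest falls. The receptor gene Gpr17 dropped 16.8-fold, from 8.20 ± 1.71 to 0.479 ± 0.115 CPM, and the growth factor receptor gene Pdgfra dropped 4.88-fold, from 41.1 ± 1.46 to 8.53 ± 2.54. Of 15 tested, 5 fell (Gpr17, Sox10, Pdgfra, Cspg4 and Olig1), 1 rose and 9 were not called, or 6 lower and 1 higher adjusted over the list alone. The riser was the myelin gene Mbp (0.78). Camera gave an adjusted p of 1.76e-09, and adjusted p = 0.231 with an estimated correlation. The median of the list, -0.15, lay well above its mean of -0.93, and Sox9 (-0.11, adjusted p = 0.662) and Ptprz1 (-0.09, adjusted p = 0.75) were among the members not called.

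Guidance receptor genes changed in both directions. Of 43 tested, 11 rose, 6 fell and 26 were not called, or 18 and 6 adjusted over the list alone and 18 and 6 in the blocked fit. Besides Unc5b, the receptor genes Dcc (0.82), Robo1 (0.71) and Nrp2 (0.58) rose, and besides Cxcr4 and Cxcr7, Epha5 fell by 1.36. Camera gave an adjusted p of 0.0629, and 0.00585 with the block, where adjusted p = 0.539 with an estimated correlation. It gave 0.00863 without KO K77, 0.0493 without WT K79 and 0.0161 without KO K80, and the number of risers was 5 without WT K77, 3 without KO K79, 4 without KO K80 and 6 without WT K80. Of 43 guidance ligand genes 9 rose, 4 fell and 30 were not called, or 12 and 6 adjusted over the list alone. Ntng1 rose by 2.63, Flrt3 by 0.72 and Rgma by 0.53, and Rgmb fell by 0.60. Camera gave an adjusted p of 0.0369 for higher levels, 0.0577 without KO K79 and 0.338 without WT K80, and adjusted p = 0.613 with an estimated correlation.

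Cell adhesion genes rose more often than they fell. Of 41 tested, 12 rose, 3 fell and 26 were not called, or 18 and 3 adjusted over the list alone. The protocadherin genes Pcdh18 (1.63), Pcdh11x (1.52) and Pcdh10 (0.73) and the cadherin gene Cdh4 (0.70) rose (camera adjusted p = 4.3e-09, and adjusted p = 0.504 with an estimated correlation). Without KO K80, 8 rose and 1 fell. Among 45 genes of the cytoskeleton and nuclear movement in migrating neurons, 7 rose, 1 fell and 37 were not called, or 8 and 2 adjusted over the list alone and 9 and 2 in the blocked fit (camera adjusted p = 0.196). Plcl1 rose by 0.74 and Dab1 by 0.53, whereas Srgap1 (0.32) lost its call without WT K77 or KO K79 (adjusted p up to 0.064) and Tuba1a (-0.38) without KO K79 (0.0749). Risers in that list numbered 2 without WT K77 or KO K79, 3 without KO K80 and 4 without WT K80, and 4 members fell without WT K79. Of 8 epithelial junction genes tested 0 were called by edgeR, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom (camera adjusted p = 0.589). The nearest were Lama5 (0.40, adjusted p = 0.16) and Epcam (0.94, adjusted p = 0.172), and 1 fell without WT K80.

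Some receptor subunits for glutamate were among the abundant genes that fell, but not all moved that way. In the authors' deposited table Grin3a (0.61), Grin2b (0.50) and Grik2 (0.39) were called higher on the log2 scale and Grik3 (-0.28) lower. The AMPA receptor genes Gria1 and Gria4 fell from 497 ± 122 to 125 ± 5.13 CPM and from 271 ± 65.2 to 137 ± 7.32 CPM, and the kainate receptor gene Grik1 fell by 1.49 on the log2 scale. In the list of GABA, glutamate and chloride handling, 5 of 37 rose, 4 fell and 28 were not called, or 7 and 5 adjusted over the list alone and 9 and 5 in the blocked fit (camera adjusted p = 0.48). The potassium channel gene Kcnj6 rose by 1.72, and 2 members rose without WT K77 or KO K80 and 3 without KO K77 or WT K79. Of 22 genes of the BMP and TGF-beta response 3 rose, 2 fell and 17 were not called, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.901). Id3, an inhibitor of basic helix-loop-helix factors, fell by 2.24. Acvr2a (0.35), Tgfbr1 (0.32) and Ski (-0.42) each lost the call without KO K79 or KO K80 (adjusted p up to 0.0589, 0.0858 and 0.101), where 0 members rose by edgeR and 1 fell. Tgfbr1 lost it without WT K77 too, and Ski without WT K77, KO K77 or WT K80, where 1 member fell. Of 24 Wnt genes 2 rose, 1 fell and 21 were not called, with the same counts adjusted over the list alone and 2 and 2 in the blocked fit (camera adjusted p = 0.922). The Wnt inhibitor gene Dkk1 rose by 2.45 and Wnt5a by 0.74, and Sfrp2 (-0.55) lost its call without any 1 KO library, WT K77 or WT K79 (adjusted p 0.0877 to 0.13). Without WT K79, 2 other Wnt genes fell.

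**Figure D2:**
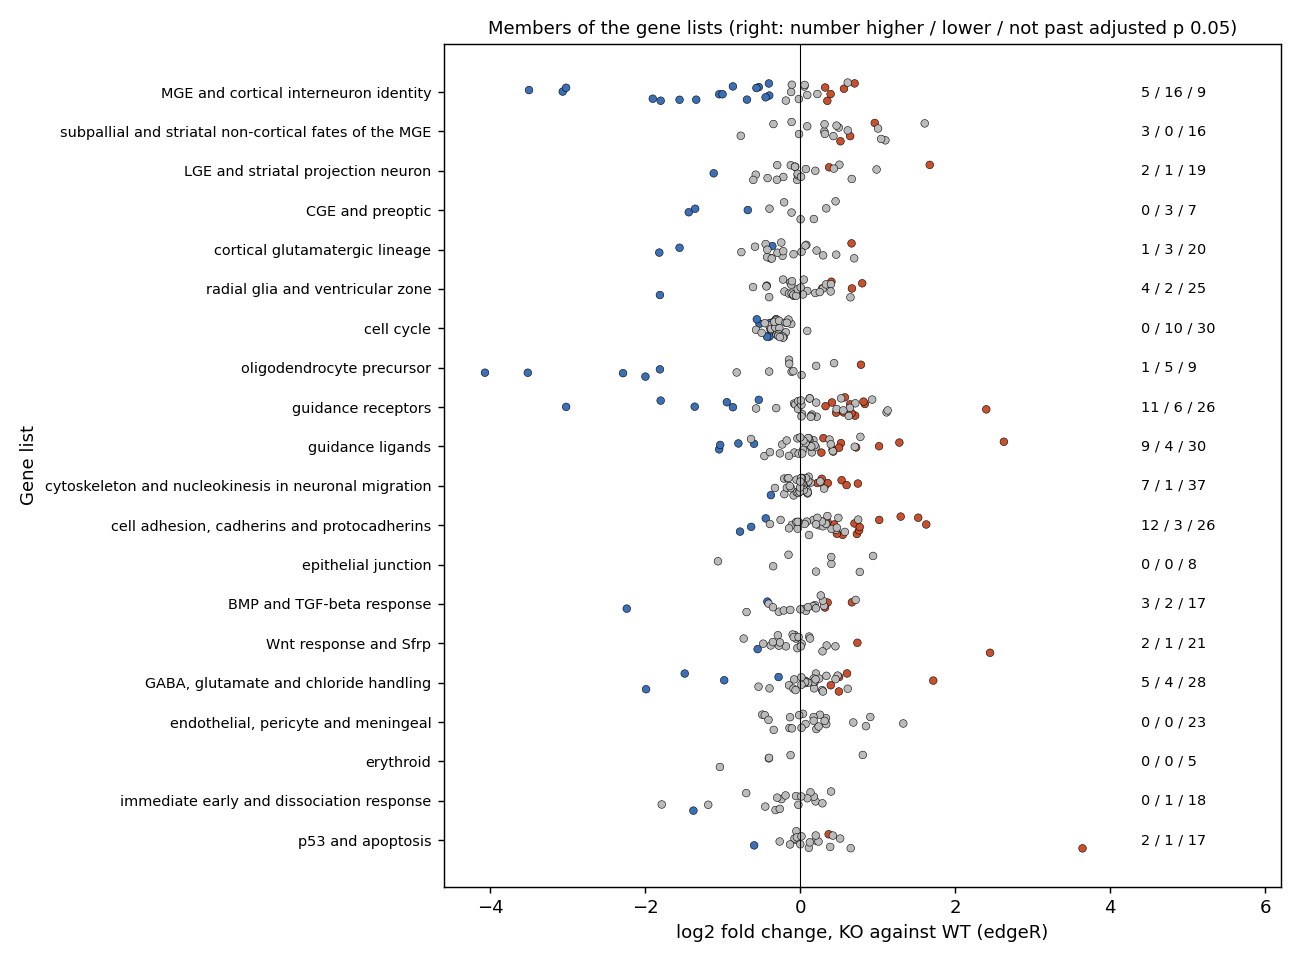
Log2 fold change of each tested member of 20 gene lists, KO against WT, with members past an edgeR adjusted p of 0.05 in orange (higher) or blue (lower), the others in grey, and the counts of higher, lower and uncalled members on the right. Interneuron identity genes had 16 members lower and 5 higher, and cell adhesion genes 12 higher and 3 lower.

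Markers of blood vessel, blood and immune cells gave no edgeR call between the genotypes in the unblocked fit with the filter on low counts. For 23 endothelial, pericyte and meningeal genes the edgeR count was 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 calls by DESeq2 or limma voom (camera adjusted p = 0.589). With no filter edgeR called 1 member of that list higher. Col1a2 had the lowest p in that list (1.33, adjusted p = 0.154), and it was called with the block (adjusted p = 0.0221), as was the embryonic globin gene Hbb-y (-1.04, adjusted p = 0.292, blocked 0.0217). Both Col1a2 and Hbb-y were also calls in the authors' deposited table. The 5 erythroid genes gave 0 calls by each tool and adjusted over the list alone, 0 of them at an unadjusted p under 0.05 (camera adjusted p = 0.589, and 0.0451 without KO K77). Only 4 microglial genes were tested, too few for camera, and edgeR called 0 of them. In that list 1 was at an unadjusted p under 0.05 and 0 passed adjusted over the list alone, by DESeq2 or by limma voom. Of 19 immediate early and dissociation genes 1 fell, 0 rose and 18 were not called, or 1 higher and 1 lower adjusted over the list alone and 1 and 3 in the blocked fit or without WT K79 (camera adjusted p = 0.4). That gene was Egr1 (-1.38), called neither with limma voom nor without WT K77, KO K79, KO K80 or WT K80 (adjusted p up to 0.172). Of 20 p53 and apoptosis genes 2 rose, 1 fell and 17 were not called, with the same counts adjusted over the list alone and 3 and 2 in the blocked fit (camera adjusted p = 0.215). The apoptosis gene Pmaip1 rose by 3.64 (SE 0.533) from 1, 7 and 5 counts in WT K77, K79 and K80, and Bcl2l11 fell by 0.60, and Ddit4 (0.37) lost its call without KO K79, KO K80 or WT K80 (adjusted p up to 0.0844).

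Hypothalamic transcription factor genes with few reads stood out in 2 of the 3 KO libraries. Hmx2 had 62 counts in KO K79 and 98 in KO K80, against 3 in KO K77 and 1, 1 and 0 in WT K77, K79 and K80. Hmx3 had 74 and 85 in those KO libraries and at most 1 in the other 4. Both were among the 14 listed members with counts that fell below the filter on low counts, and with no filter edgeR called 5 higher and 0 lower, namely Hmx2, Hmx3, Six6, Bsx and Lhx5. The 4 members above the filter, too few for camera, gave 0 calls by edgeR, 2 at an unadjusted p under 0.05, 1 adjusted over the list alone, 1 by DESeq2, 0 by limma voom and 1 in the blocked fit. That member was Lhx5 (1.91, adjusted p = 0.0666, blocked 0.0427, and 0.014 without KO K77). Hmx2 and Hmx3 were also listed for the caudal eminence and preoptic area, where 4 members rose with no filter. The authors' deposited table listed Hmx2 at a log2 fold change of 6.23 and Hmx3 at 6.30. Sox14 and Otx2, outside the lists and chosen after their values were seen, also had their highest counts in KO K79 (26 and 329) and KO K80 (31 and 350). Otx2 was not confined to them, with 153 counts in WT K79 and 125 in KO K77. The listed gene Fezf1 had 22 counts in WT K79 and 22 in KO K80.

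The libraries differed in sex-linked transcripts. WT K79 held 26109 Xist counts and 6 counts over 4 Y-linked genes, whereas the other 5 libraries held 13 to 28 Xist counts and 2651 to 3745 Y-linked counts. Of the 5 sex-linked genes tested, edgeR called 0, with 1 at an unadjusted p under 0.05, 1 lower adjusted over the list alone, 0 by DESeq2 or limma voom and 1 in the blocked fit (Xist, 0.00375). Reads of Xist and its antisense partner Tsix are uncertain for want of a strand. All 15 mitochondrially encoded genes had 0 counts in each library, so that list was not tested.

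The authors' deposited table, a comparison of KO with WT, listed 1202 genes at an adjusted p under 0.05, 731 higher and 471 lower in KO. Of the calls in the authors' deposited table, 777 were called by edgeR here with the same sign, 343 were tested and not called, and 82 were below the filter on low counts. Another 90 genes were called by edgeR and not in the authors' deposited table. Of the calls in the authors' deposited table, 200 (16.6%) were genes whose KO and WT libraries overlapped. Xist was 1 of them, with a log2 fold change of -8.74 in the authors' deposited table that rested on WT K79 alone, against an edgeR adjusted p of 0.0803.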

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

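The fits without both K79 libraries and with the block plus an estimated correlation were chosen after the data had been seen. Changed genes numbered 867 (504 higher, 363 lower) by edgeR and 1463 (848 and 615) with the K number as a block, which put 8 lists past the threshold in place of 7, kept all 867 calls and changed no other call of a named gene or list than those given in the report. They numbered 427 (254 and 173) at adjusted p under 0.01, and lower genes 557 at 0.1 and 546 with no filter on low counts, as looser limits and more genes tested would give. Leaving out 1 library gave 445 to 1044 changed genes, 270 to 645 higher and 175 to 399 lower, the smaller totals being 528 without WT K77, 498 without KO K79 and 445 without KO K80, with fewer libraries in the fit. Without WT K79 749 of the 867 calls were kept, without both K79 libraries 555, by DESeq2 786 and by limma voom 840, and in the settings run no call changed sign. Of the 7 lists, 0 passed with an estimated correlation, 1 with fry and 0 with the block and an estimated correlation, the cause of which was not tested. Over the 91 named genes, with Zeb2 left out of this tally, there were 1257 combinations of gene and setting. Of these, 1155 kept their side of the threshold, 95 lost it, 7 gained it and 0 reversed. A combination without an adjusted p was counted as kept. Hbb-y had no value with the erythroid rows dropped, and Slc4a1 had none there or without both K79 libraries. At this depth the simulated fit recovered 55.1% of genes changed 1.5-fold, so smaller changes can be missed.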

Other observations

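The imprinted gene list and each test on it, the tests on WT K79, and the test of oligodendrocyte precursor genes without WT K79 were chosen after the results had been seen, and the held-out precursor genes were chosen after the calls had been seen, with their bound set before their median was computed.

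Imprinted genes, expressed from 1 parental copy, rose more often than tested genes as a whole, on a list written after the calls had been seen. Of 43 members 39 were tested, 14 rose, 1 fell and 24 were not called, against 3.64% of all tested genes called higher. The risers included Meg3 (1220 ± 185 to 2301 ± 136 CPM), Peg3 (531 ± 80.7 to 1193 ± 212), Mest (149 ± 18.5 to 327 ± 18.2) and Zdbf2 (130 ± 26.1 to 322 ± 64.6), each with n = 3. Magel2 rose by 1.17 on the log2 scale, Rtl1 by 1.83, Ndn by 0.70 and Nnat by 0.45, and H19 fell by 0.76, a call lost without KO K79 or KO K80. The camera p was 9.13e-20 and p = 0.015 with an estimated correlation. Fli1 and the related gene Ets1, neighbours in the GRCm38.p6 gene order with 0 protein-coding genes between them (Ets1 being chosen after its values were seen), moved apart, Ets1 falling by 1.88 (SE 0.22, edgeR adjusted p = 0.000845).

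The rise of imprinted genes was set against 3 technical readings. Without WT K79, the library with abundant Xist, 14 of the 14 risers stayed past the threshold. That library lay nearest to KO among the WT libraries, so leaving it out could hardly cost calls, and 17 members rose in that fit. Members called higher numbered 12 without WT K77, KO K79 or KO K80, 13 without WT K80 and 15 without KO K77. The risers fell into 8 neighbour groups, which argues against reads shared within a single cluster, although overlapping genes inside a cluster stay uncertain. The median of the list, 0.235 (95% interval from resampled genes 0.116 to 0.465), decides nothing on scaling, because scaling itself puts the median of all genes near 0 (-0.00582). The list was written after some of its members had been seen, so a coordinated response to the loss of Zeb2 may be a hypothesis only. A change in the mix of sorted cells stays open. Hmx2 and Hmx3 had 62 to 98 counts in KO K79 and KO K80 and at most 3 in the other 4 libraries. Imprinted genes shared that pattern only in part. In KO K77, KO K79 and KO K80, Zim1 stood at 11.9, 25.6 and 34.6 CPM, but Dlk1 at 346, 376 and 398 CPM.

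The 5 oligodendrocyte precursor genes called lower fell to between 5.95% (Gpr17) and 28.5% (Olig1) of WT, and without WT K79 5 of 5 stayed called. Fewer precursor cells in the KO sort should give a median of -1 or lower over held-out precursor genes, with a median above -0.5 set to count against it, and the 7 of 15 that could be tested had a median log2 fold change of -0.00428 (95% interval -0.193 to 0.00759). An earlier version, 22 genes with 13 tested, gave 0.00465 (-0.119 to 0.0896), with Sox3 higher (0.90, adjusted p = 0.034), Chst2 not called (0.34, adjusted p = 0.0909) and Matn4 lower (-3.48). Before the test Matn4 was dropped for having been seen among the calls, and Sox3 and Chst2 with 4 others as less specific, and the 15 genes with Matn4 put back, chosen later, gave -0.0618 (-0.406 to 0.00759, 8 tested). The 3 medians and their intervals, which resample genes, lay above the bound, but they decide nothing on a loss of precursor cells. The versions were chosen after the calls had been seen. Vcan stood at 725 CPM in WT against 41.1 for Pdgfra, so it need not follow a small share of the cells. Matn4, at 3.16 CPM in WT, was the 1 held-out gene called lower. Whether the held-out genes mark such cells at this age was not tested. A loss of precursor cells and lower expression of the 5 genes within them both stay open.

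Among WT libraries, WT K79 lay nearest to KO. Over 344 genes called without it and changed at least 2-fold, WT K79 stood 32.6% (95% interval 28.6 to 35.4) of the way from the other WT libraries to KO on the log2 scale. Placed in the same way, WT K77 stood at -5.92% over 198 genes and WT K80 at -6.04% over 202 genes. WT K79 was part of the WT end for both, so the values do not share an axis. The 95% interval for WT K79, and those for the mixing shares below, resample genes and hold no spread between libraries. Material of the KO libraries sequenced here would bring Y-linked counts. Those in WT K79 reached 0.205% (counting interval 0.0752 to 0.446) of the lowest KO library, against a mixing share of at least 17.4%. KO K79 lay 5.33% of the way from KO to WT, between KO K80 (-0.121%) and KO K77 (9.75%). Each was placed over its own genes and axis, and 1 KO library must lie between the others. A shift shared by the K79 libraries stays open, as their deviations from the group means were correlated (0.197). Other KO material without Y-linked reads stays open, because shares of 44.2% (37.8 to 49.2) from genes lower and 22.0% (17.4 to 27.2) from genes higher in KO lay 22.2 points apart, no more than in WT K80 (34.3) or KO K77 (25.1). Sex cannot be told apart from other features of that library, as 1 library had abundant Xist, and differences in dissection were not tested. Zeb2 itself stood at 513 CPM in WT K79, against 705 in WT K77, 768 in WT K80 and 272 to 343 in the KO libraries. Whether that lower Zeb2 level bears on the place of WT K79 was not tested.

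The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, the real split gave 867 and the highest other 0 by edgeR (175 to 1048 at an unadjusted p under 0.05), and 1 of the 10, the real one, gave as many. Each other split put KO and WT libraries on both sides, which widens the spread within a side, so few gene calls were likely in advance. For lists, the real split gave 7 and the highest other 14, and 7 of the 10 gave as many. The 14 came from WT K77, WT K79 and KO K79 against the rest, so list calls with a preset correlation also follow differences between libraries other than genotype. Among the splits that part the 3 pairs, the others gave 0 genes and 3 to 9 lists.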
